A study of Homo sapiens with 26 samples.

How the data were processed

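HCT116, a human colorectal cancer cell line, was used throughout. ChIP-seq with a FLAG antibody was run on 7 libraries and 7 matching input libraries, from clonal lines that stably express FLAG-tagged ZBTB24, FLAG-tagged DNMT3B or the tag alone. RNA-seq was run on 12 libraries, of which 3 carried a non-targeting hairpin (shNT), 3 a hairpin against ZBTB24 (shZBTB24), 2 the tag alone, 2 FLAG-ZBTB24, 1 came from a DNMT3B knockout line and 1 from wild-type cells. Groups and replicate numbers came from the sample titles. Per the labels' protocols, lentiviral lines were selected with puromycin and the FLAG lines were grown from single cells, so differences between clones stay with the groups. Nothing in the labels says that the hairpin replicates came from separate cultures, so the authors' p-values for the knockdown measure only the spread between these libraries, which may be technical. The FLAG libraries carry different line numbers in their titles, so the p-values of that comparison may also hold spread between clones. The knockout comparison, with 1 library per group, has no spread between libraries to measure. The RNA libraries were made with a stranded total RNA kit, per the labels' protocols.

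The submitters' processing notes name HISAT2, StringTie, Cufflinks and MACS2 and the hg19 build, and their versions are not given in the sources used here. The expression tables hold 1 pooled FPKM value per group, as the authors deposited them. Each of these deposited tables also gives a log2 fold change of the second group over the first. The p-value and q-value of each locus are those the authors deposited. Both peak lists carry 1 score per peak from the authors, and the kind of score is not given in the sources used here. The merged peak lists hold 1 set of peaks per factor and no peaks per library. No table gives values per library, so no standard deviation, standard error or sequencing depth could be given for any value, and no test across libraries was run. The depth behind each FPKM value is unknown.

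The 3 expression tables list only part of the loci tested. The shZBTB24 table held 1965 loci, each with an absolute log2 fold change above 0.50 and a p of at most 0.0549. The p and q of its loci fit an adjustment over 29309 tests better than over any other number tried. The FLAG-ZBTB24 table held 1754 loci above the same fold change, with a p of up to 0.839. The knockout comparison gave 2243 loci that name the DNMT3B knockout, all higher and with log2 fold changes of at least 1.00. A locus that is absent from a table was therefore either unchanged, filtered out or not tested, and these cannot be told apart. Another 1112 rows of the knockout table carry the label DNMT3BKOshZB, which matches no sample given here, and all of them were lower than wild type. They were left out of the main comparisons and counted only in 1 alternative, and some of their values stand in the closing section. A locus with several gene symbols was counted once, because its reads cannot be assigned to one gene. The assembler's identifiers were shared between the shZBTB24 and knockout tables and not with the FLAG-ZBTB24 table, so tables were joined by gene symbols. Of the gene symbols, 99.9% of the shZBTB24 table, 100% of the FLAG-ZBTB24 table and 99.9% of the knockout table were found in the assembled annotation, and 3 symbols had been turned into dates. No column was left without a group or comparison.

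A locus was past the threshold where the q of the authors' deposited table was under 0.05. The rule for named genes, the alternatives and the 32 gene lists were fixed before the data were examined, except where said otherwise. Lists with at least 5 listed loci were tested per direction with a two-sided Fisher's exact test against the other loci of the table, with Benjamini-Hochberg adjustment over 75 tests. The median fold change of a list was also ranked among 10000 random lists of the same size drawn from 10 bins of mean expression. Fold changes were correlated across loci found in both of 2 tables, with 100000 resamples, for 3 pairs of tables. Loci are not independent replicates, and co-regulated genes make such p-values too small. The knockout and the wild type had 1 library each, so p-values across loci, although planned, are not given for that table, and its q compares those libraries and not the conditions. It is not known whether FPKM values were normalized together across tables, so levels set side by side across them are descriptive.

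A peak lay at a promoter where its midpoint was within 1000 bp of a transcript start of the assembled annotation, and in a gene body where it was inside a transcript and farther from any start. Shares carry 95% Wilson intervals, which cover counting error only, and, where a count was 0, also the share that 3 counts would give. Shares were set against 1000 random placements of the same peaks within their chromosomes, two-sided. Positions ran up to the last annotated base of each chromosome, and gaps in the genome were not left out. This can lower the shares that placements give at promoters and in gene bodies. The smallest p these placements can give is 0.002. Genes were called bound from 51116 reference transcripts of 26281 named genes, by a ZBTB24 peak at the promoter or a DNMT3B peak in the body or at the promoter. Median fold changes of bound and unbound loci were compared with 100000 resamples, two-sided. BED starts were raised by 1 to give 1-based hg19 coordinates. The annotation marks exons and no untranslated regions. Genomic sequence was not used here.

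The named genes follow a fixed rule. It takes ZBTB24, DNMT3B, CDCA7, HELLS, DNMT1, DNMT3A and UHRF1 where listed. It takes the 12 largest rises and the 12 largest falls per table past the threshold with at least 1 FPKM in one group, leaving out XIST and Y-linked genes. It also takes up to 4 loci past the threshold per list, the 10 highest-scoring peaks of each factor, and loci with a ZBTB24 promoter peak past the threshold in both of 2 tables. Some items that the rule takes are not reported here. A list of reported ZBTB24 targets was also looked up at the peaks and in the tables. The alternatives were other fold-change thresholds, only loci with a symbol, only loci with at least 1 FPKM, correlations without the 1% largest changes, pseudocounts of 1 and 0.1, promoter windows of 500 and 2500 bp, peaks at or above the median score, reference transcripts only, other definitions of overlap and means in place of medians.

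The tests were run on simulated data first. With 1 log2 unit added to the bound loci, the difference of medians found the shift in 19 of 20 draws in the shZBTB24 table, in 10 of 20 draws in the FLAG-ZBTB24 table and in 20 of 20 draws in the knockout table. The difference of means found it in 20 of 20 draws in each table. Without a shift, the medians made 2 calls in 20 draws in the FLAG-ZBTB24 table and the means 2 in the shZBTB24 table, and 0 in the other cases. The shift put some loci of the shZBTB24 and FLAG-ZBTB24 tables near 0, where the real tables hold none. It was also larger than the difference of medians of 0.05 in the knockdown, so the draws do not show whether such a difference would be found. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.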

Results

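ZBTB24, a zinc finger protein mutated in ICF syndrome, and DNMT3B, a de novo DNA methyltransferase mutated in the same syndrome, were mapped and perturbed in HCT116 cells. Binding was measured by FLAG ChIP-seq in 3 FLAG-ZBTB24, 2 FLAG-DNMT3B and 2 FLAG-only lines. Expression was measured by RNA-seq after ZBTB24 knockdown (3 libraries against 3 with a non-targeting hairpin), in cells with added FLAG-ZBTB24 (2 against 2 with the tag alone) and in 1 DNMT3B knockout library against 1 wild-type library. All expression values below are pooled per group, so no error between libraries is given.

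Knockdown of ZBTB24 was followed by a rise of interferon-stimulated genes. Of the 45 genes on that list, 33 loci were in the authors' deposited table, all 33 with higher values, and 25 of them rose past the threshold. RSAD2, which encodes the antiviral protein viperin, rose from 0.0629 to 1.01 FPKM in the authors' deposited table (log2 fold change 4.01, q = 0.034). The locus of IFI44 and IFI44L rose from 2.94 to 31.1 FPKM in the authors' deposited table (log2 fold change 3.40), and OAS1, a sensor of double-stranded RNA, rose from 3.13 to 22.1 FPKM (log2 fold change 2.82). SAMD9 rose from 2.44 to 16.5 FPKM and IFI6 from 46.0 to 302 FPKM in the authors' deposited table. The list held more risen loci than the rest of the table (Fisher's exact test, adjusted p = 2.0e-15), and its median log2 fold change of 1.65 stood at percentile 100 of random lists.

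Over the whole authors' deposited table for the knockdown, 433 loci passed the threshold, of which 240 rose and 193 fell. At least 2-fold changes were seen for 149 of the risen and 116 of the fallen loci in the authors' deposited table. ZBTB24 itself was not among the listed loci, so the knockdown could not be checked in these values. CDCA7, HELLS, DNMT1, DNMT3A, DNMT3B and UHRF1 were not listed either. The largest rise past the threshold in the authors' deposited table was at the locus of the long non-coding RNA PVT1 with MIR1204 and MIR1206, from 190 to 20731 FPKM (log2 fold change 6.77, q = 0.00493). Outside the interferon list, RASGRP3 (log2 fold change 3.21), NRG1 (3.10), ELF5 (3.08), FAM111B (2.70) and NME5 (2.68) were among the 12 largest rises past the threshold in the authors' deposited table. The largest fall past the threshold in the authors' deposited table was at the locus of SNHG17 and SNORA71A to SNORA71C, from 136 to 12.8 FPKM (log2 fold change -3.41, q = 0.00493). Both the PVT1 and the SNHG17 locus hold small RNA genes, where unstable FPKM values cannot be told apart from a change. PGM5 (log2 fold change -2.67), the collagenase gene MMP1 (-2.19), ATP8B3 (-2.16), CNTNAP2 (-2.08) and the neuropeptide precursor gene VGF (-1.88) also fell in the authors' deposited table.

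**Figure D1:**
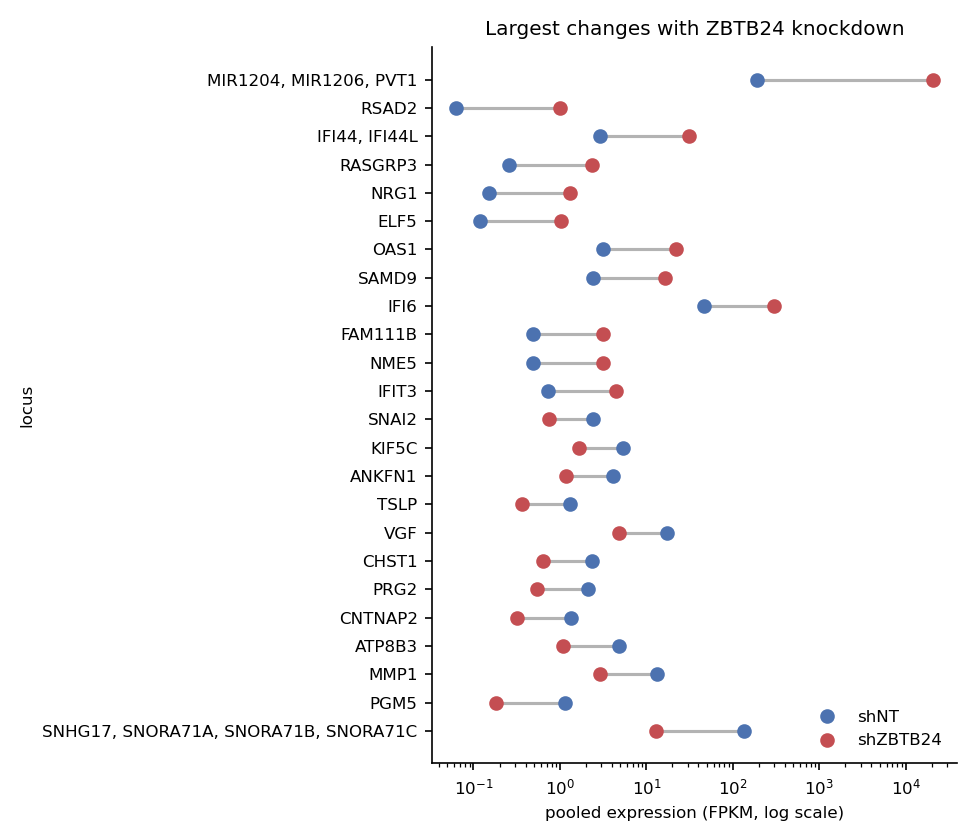
Pooled expression in FPKM (log axis) of the 12 largest rises and 12 largest falls with ZBTB24 knockdown, 1 line per locus, in shNT (blue) and shZBTB24 (red), from the authors' deposited table. The PVT1 locus moved from 190 to 20731 FPKM and the SNHG17 locus from 136 to 12.8 FPKM.

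Listed genes of DNA replication and of mitosis mostly lay in opposite directions after the knockdown. All 18 listed S phase loci had higher values in the authors' deposited table and 6 rose, among them MCM4, a subunit of the replicative helicase, from 6.46 to 19.5 FPKM, and GINS2 from 5.73 to 14.6 FPKM. Of 16 listed G2 and M phase loci in the authors' deposited table, 14 had lower values and 3 fell, among them CDC20 from 92.6 to 49.0 FPKM and UBE2C from 73.5 to 39.4 FPKM. After adjustment, no excess of called loci was detected for either list (adjusted p = 0.243 for S phase rises and 1 for G2 and M phase falls, Fisher's exact test). Of all 1965 listed loci, 240 rose and 193 fell in the authors' deposited table. In a test of the direction of all listed loci, chosen after seeing the data, both lists stood apart from the rest of the table (Fisher's exact test, adjusted p = 0.000166 for S phase and 0.00195 for G2 and M phase). All 13 listed genes of the unfolded protein response and ATF4 pathway had lower values in the authors' deposited table and 4 fell, with SLC7A11, a cystine transporter, at a log2 fold change of -1.15 and ASNS, asparagine synthetase, at -1.04. For that list an excess of falls was not detected after adjustment (adjusted p = 0.34, Fisher's exact test), while its direction differed (adjusted p = 0.000166, Fisher's exact test). All 13 listed ribosomal protein loci also had lower values with the knockdown in the authors' deposited table, 0 past the threshold and 13 at an unadjusted p under 0.05. All 5 listed cholesterol synthesis genes had lower values in the authors' deposited table and 3 fell, among them INSIG1 (log2 fold change -1.46) and MSMO1 (-1.11). The adjusted p of that list was 0.151 for falls and 0.0315 in the test of direction (Fisher's exact test for each). Of 77 listed zinc finger genes named ZNF, 65 had higher values in the authors' deposited table, 8 rose, including ZNF234 (log2 fold change 2.36) and ZNF107 (1.63), and 0 fell, fewer falls than in the rest of the table (adjusted p = 0.0146, Fisher's exact test). At an unadjusted p under 0.05, 64 of the higher and 10 of the lower zinc finger loci passed in the authors' deposited table. Adjusted over the list alone, all 33 interferon-stimulated, 18 S phase, 16 G2 and M phase, 13 unfolded protein response and 5 cholesterol loci passed, and 62 higher and 8 lower zinc finger loci did. That count is set mostly by what was listed, since 1907 of the 1965 loci in the authors' deposited table had a p under 0.05.

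**Figure D2:**
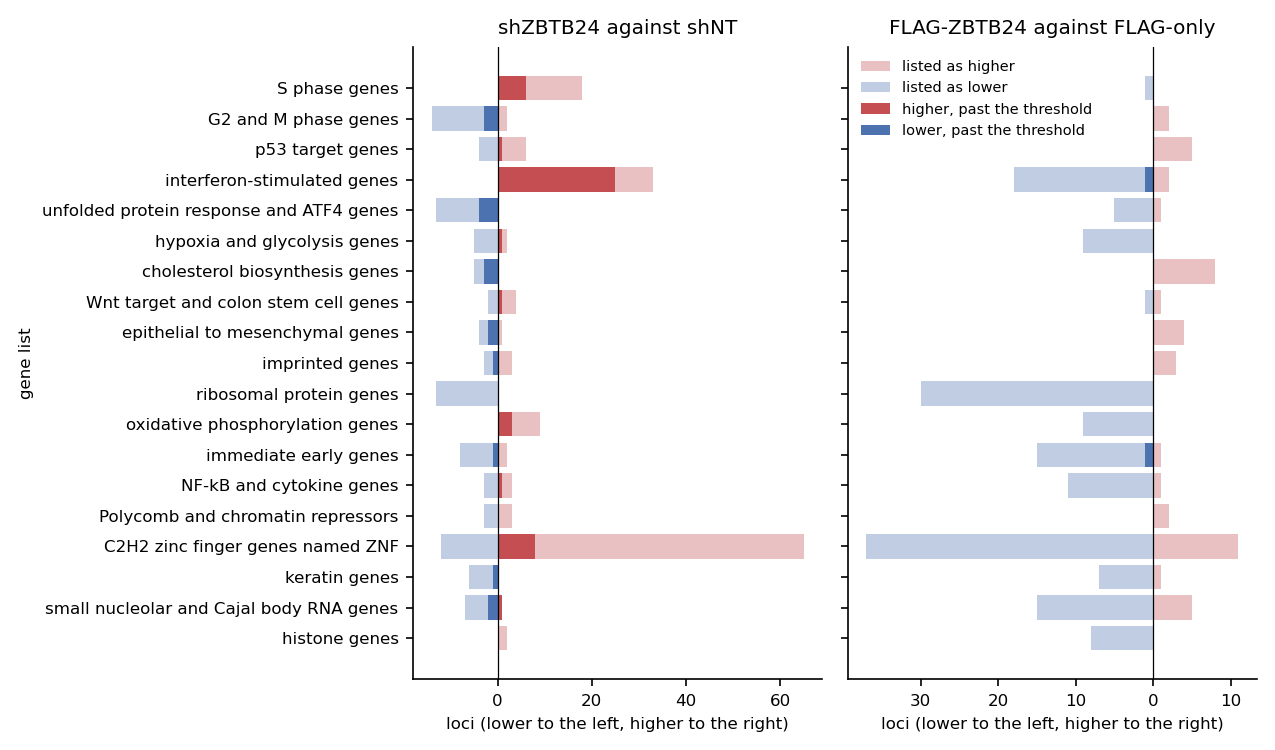
Number of listed loci per gene list with higher values (red, right) and lower values (blue, left) in the authors' deposited tables for shZBTB24 and FLAG-ZBTB24; the dark part of each bar is past the threshold. With knockdown 33 interferon-stimulated loci lay on the higher side, and with FLAG-ZBTB24 18 of 20 lay on the lower side.

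Addition of FLAG-ZBTB24 changed few loci past the threshold. The locus that holds ZBTB24 together with its neighbour MICAL1 rose from 17.8 to 155 FPKM in the authors' deposited table (log2 fold change 3.12, q = 0.0192), and reads of these genes cannot be told apart. In all, 4 loci rose and 6 fell in the authors' deposited table. EDA2R, a receptor of the tumor necrosis factor family, rose from 0.506 to 5.20 FPKM in the authors' deposited table. DNAH2, named after its values were seen, rose from 0.0959 to 0.79 FPKM in the authors' deposited table, and 1 locus was left out by the rule for named genes. At an unadjusted p under 0.05, 174 loci of the authors' deposited table passed. The metallothionein genes MT1X (log2 fold change -3.28), MT1E (-2.65) and MT2A (-2.10), the prostaglandin-degrading enzyme gene HPGD (-3.22), the interferon-stimulated gene IFI27 (-2.39) and JUNB (-1.67) fell in the authors' deposited table. These FLAG lines were grown from single cells, so differences between clones stay with the groups.

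Of several lists, most of the loci listed for the FLAG-ZBTB24 lines lay on one side, most of them not past the threshold. All 30 listed ribosomal protein loci and 18 of 20 listed interferon-stimulated loci had lower values in the authors' deposited table, of which 0 and 1 passed the threshold; at an unadjusted p under 0.05 these were 6 and 7 loci. The listed ribosomal protein loci thus lay on the lower side in both tables, 13 with the knockdown and 30 with FLAG-ZBTB24. Loci with a p of up to 0.839 were listed for FLAG-ZBTB24 and of up to 0.0549 for the knockdown, so the listed counts are not alike. Other lists lay on opposite sides, since 37 of 48 listed zinc finger genes and all 9 listed oxidative phosphorylation genes had lower values with FLAG-ZBTB24 in the authors' deposited table, 0 of either past the threshold and 3 of each at an unadjusted p under 0.05, while 65 of 77 and all 9 had higher values with the knockdown. In the test of direction, chosen after seeing the data, adjusted p with FLAG-ZBTB24 was 0.00195 for zinc finger, 0.0101 for oxidative phosphorylation and 6.9e-08 for ribosomal protein genes (Fisher's exact test). Ranked among random lists matched on expression, their medians with FLAG-ZBTB24 stood at percentiles 0.66, 18.2 and 37.5, in that order. With the knockdown these were 99.99, 84.1 and 16.8. The oxidative phosphorylation and ribosomal protein medians thus did not stand apart from loci of like expression. Among immediate early genes 15 of 16 listed loci had lower values in the authors' deposited table, and 1 fell. All 8 listed cholesterol synthesis loci had higher values in the authors' deposited table and 0 passed, with 1 at an unadjusted p under 0.05. Adjusted over the list alone, 3 interferon-stimulated, 3 immediate early, 0 ribosomal protein and 0 cholesterol loci passed. An excess of called loci was not detected for any list of this table after adjustment.

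In the DNMT3B knockout library, 7 loci were past the threshold in the authors' deposited table, all of them higher than in wild type. DHRS2, a short-chain dehydrogenase gene, was at 20.6 FPKM in wild type and 2833 FPKM in the knockout in the authors' deposited table (log2 fold change 7.10). NOTUM, a secreted Wnt inhibitor, was at 4.96 and 192 FPKM, ISG15 at 35.1 and 867 FPKM and OAS3 at 8.29 and 150 FPKM in the authors' deposited table. COL6A1 (log2 fold change 3.62), the locus of IFITM1 and IFITM2 (3.17) and the locus of LRCH4, SAP25 and ZASP (4.39) were the others in the authors' deposited table. DNMT3B was not listed under the knockout's label, so the knockout could not be checked there; under the label DNMT3BKOshZB it was listed at 21.1 FPKM in wild type and 6.46 FPKM in the authors' deposited table (q = 0.676), and DNMT3A was listed at 3.25 and 8.47 FPKM in the authors' deposited table without passing the threshold (q = 0.722). In that table the labels split exactly by direction, since all 2243 loci labelled as the knockout were higher and all 1112 loci with the label DNMT3BKOshZB were lower in the authors' deposited table. Named loci with equal p had equal q under both labels, and the highest q was also equal, so both labels may share a single adjustment. Falls of the knockout may therefore stand under the other label, and the absence of falls here is no result. With 1 library per group, these differences have no replicate check, and 56.8% of the listed loci had a wild-type value under 1 FPKM in the authors' deposited table.

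Of the 45 interferon-stimulated genes, 41 loci were listed as higher in the knockout in the authors' deposited table, 3 of them past the threshold, and their median log2 fold change of 4.56 stood at percentile 100 of random lists of that table. The knockout table also listed 17 loci of antigen presentation (median log2 fold change 3.05), 9 cancer-testis and germline loci (6.61), 16 NF-kB and cytokine loci (2.67) and 9 HOX loci (2.05), none past the threshold in the authors' deposited table. Among random lists of that table, these 4 medians stood at percentiles 98.1, 99.97, 92.9 and 66.7, in the same order. The median of the HOX loci thus did not stand apart. Of the loci of each list found in any of the 3 tables, 95.3% of the interferon-stimulated, 89.5% of the antigen presentation and 100% of the cancer-testis loci were among the knockout rises, against 45.2%, 45.4% and 45.5% of the other loci. Counts of loci that pass when adjusted over a list alone are not given for the knockout table, because neither group had a replicate library.

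**Figure D3:**
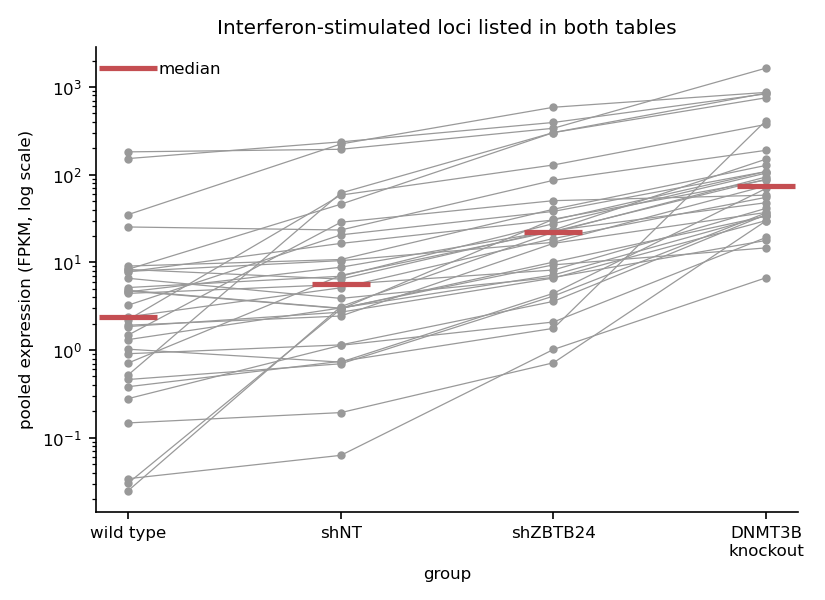
Pooled expression in FPKM (log axis) of the 33 interferon-stimulated loci listed in both the shZBTB24 and the knockout tables of the authors, 1 line per locus, with the median as a red bar. Lines only link a locus across groups, and it is not known whether the tables were normalized together. All loci were listed as higher in the knockout than in wild type, so the choice favours low wild-type values. The medians were 2.39 FPKM in wild type, 5.59 in shNT, 22.1 in shZBTB24 and 74.6 in the knockout.

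Fold changes of the 3 tables were then compared at shared loci, to ask whether loss of ZBTB24, gain of ZBTB24 and loss of DNMT3B move the same genes. Over 365 loci listed for both shZBTB24 and FLAG-ZBTB24 no correlation of fold changes was detected (Pearson's r = -0.04, permutation p = 0.485, adjusted p = 0.485; Spearman's rho = -0.07, p = 0.205). With at least 1 FPKM in either group, rho was -0.12 (permutation p = 0.0386, unadjusted). In a test of direction chosen after seeing the data, the share of these 365 shared loci with lower values for FLAG-ZBTB24 was 70.6% where the knockdown value was higher and 56.1% where it was lower (Fisher's exact test, odds ratio 0.533, p = 0.00457), and without the interferon-stimulated loci p was 0.0202. Among the shared loci, 4 rose with the knockdown and fell with FLAG-ZBTB24 (Fisher's exact test, p = 0.000717, adjusted p = 0.00287 over 4 pairs of directions). These were IFI27, MT1E, MT2A and HPGD, with log2 fold changes of 2.29, 2.08, 1.39 and 1.13 for the knockdown in the authors' deposited table. Over 379 loci listed for both the knockdown and the knockout, r was 0.17 and rho 0.04. Without the 1% largest changes r was 0.01, and with at least 1 FPKM in either group r was 0.29 and rho 0.11. For FLAG-ZBTB24 and the knockout, r was -0.11 and rho -0.10 over 407 loci. Without the 1% largest changes r was -0.04, and with at least 1 FPKM in either group r was -0.14 and rho -0.15. The knockout side of both comparisons holds rises only. OAS3 and ISG15 were past the threshold as rises in both the knockdown and the knockout, and DHRS2 fell from 27.8 to 14.8 FPKM in the knockdown and was higher in the knockout in the authors' deposited tables. OAS3 was the one locus past the threshold in both that also had a ZBTB24 promoter peak.

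ZBTB24 peaks lay at promoters more often than chance placement gives. The authors' merged list held 6173 ZBTB24 peaks with a median width of 191 bp, of which 1142 (18.5%, 95% interval 17.6% to 19.5%) lay within 1000 bp of a transcript start, against 4.69% of random placements (permutation of positions, p = 0.002). Another 1721 peaks (27.9%, 26.8% to 29.0%) lay in gene bodies, against 43.6% of placements (permutation of positions, p = 0.002). The highest score given by the authors, 55.4, belonged to a peak on chromosome 2 from 174219128 to 174219679, whose midpoint was 158 bp from the start of CDCA7, another ICF syndrome gene. Next came the promoter peaks of RIOK2 (chromosome 5, 96518890 to 96519399, score 49.98), CDC40 (chromosome 6, 110501258 to 110501976, score 49.7) and RPL32 (chromosome 3, 12882931 to 12883422, score 48.0). The promoter peak of TAF6 (chromosome 7, 99716841 to 99717317, score 43.1), an intron peak in TAOK3 and peaks between genes nearest to IL20RA, LINC01324 and LINC00473 were also among the 10 highest. ZBTB24's own promoter held a peak with a score of 8.03, and no peak lay at the promoters of DNMT3B, HELLS, DNMT1, DNMT3A or UHRF1. All 7 genes on a list of reported ZBTB24 targets held a promoter peak, namely CDCA7, TAF6, CNPY4, CDC40, OSTC, RNF169 and CAMKMT, with TAF6 and CNPY4 sharing 1 peak. That list may rest on these same libraries, so it is not independent evidence. Of its members, CAMKMT (6.68 and 10.8 FPKM, q = 0.366) and RNF169 (13.4 and 9.01 FPKM, q = 0.208) were listed for the knockdown, OSTC (108 and 74.9 FPKM, q = 0.967) for FLAG-ZBTB24, CNPY4 (1.63 and 4.87 FPKM, q = 0.984) for the knockout and CDCA7 (36.9 and 13.3 FPKM, q = 0.559) under the label DNMT3BKOshZB in the authors' deposited tables, none past the threshold.

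Most DNMT3B peaks lay in gene bodies, and 22.3% of the reference genes held one in the body or at the promoter. Of 15909 DNMT3B peaks, with a median width of 2482 bp, 14504 (91.2%, 95% interval 90.7% to 91.6%) lay in gene bodies, against 44.1% of random placements (permutation of positions, p = 0.002). At promoters lay 1261 (7.93%, 7.52% to 8.36%), against 5.21% of placements (permutation of positions, p = 0.002). The promoter result turned with the annotation, because with reference transcripts only 0.754% of the peaks lay at promoters, below the 2.06% of placements. The highest scores given by the authors were 5.41 in an intron of ARPC2 (chromosome 2, 219117874 to 219119045), 4.82 in an intron of ZNF131 (chromosome 5, 43163719 to 43164874) and 4.81 in an intron of HMGXB3 (chromosome 5, 149425220 to 149430746). Of the 10 highest peaks the others lay inside CRYZL1, CROCC, TAMM41, PTPN9, MTMR14 and TAF15, and 1 lay in an assembled intron 7202 bp from the start of USP49.

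**Figure D4:**
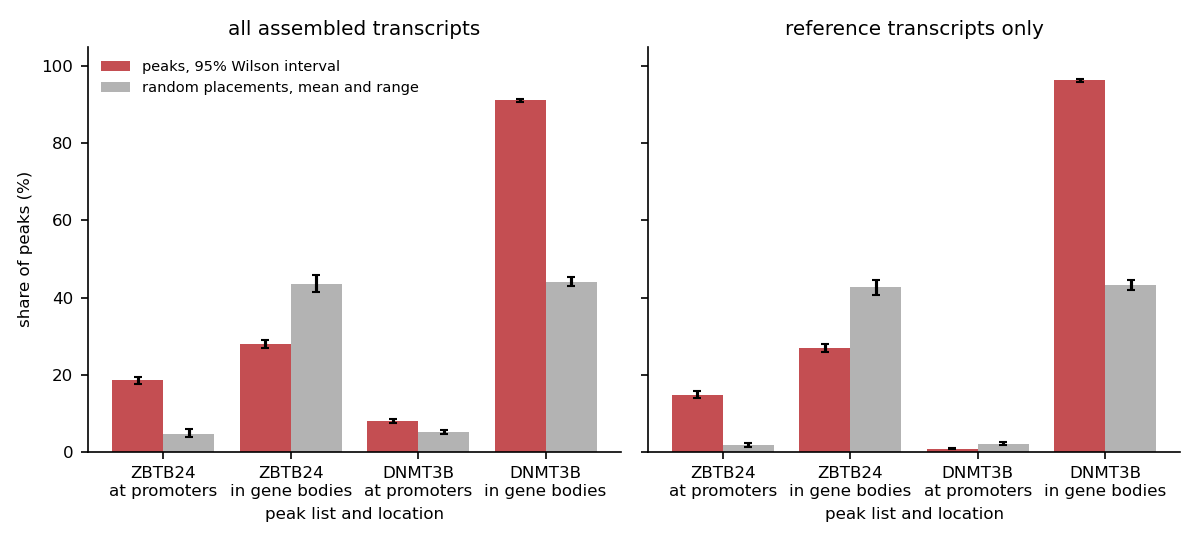
Share of ZBTB24 and DNMT3B peaks (percent, from 0) at promoters and in gene bodies, with 95% Wilson intervals (red), beside 1000 random placements with their mean and range (grey), for all assembled transcripts and for reference transcripts only. DNMT3B peaks in gene bodies made up 91.2% and 96.3%, and its promoter share was above placement in the first panel and below it in the second.

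The 2 factors rarely occupied the same sites. Only 5 of the 6173 ZBTB24 peaks (0.081%, 0.0346% to 0.189%) overlapped a DNMT3B peak, against a mean of 132 in random placements (range 104 to 167, permutation of positions, p = 0.002). When each peak was moved to another transcript start at the same distance, a mean of 305 overlapped (range 254 to 368, permutation of positions, p = 0.002). These 5 peaks lay inside SDHA, SDHAP3, RAP1GAP2, EIF3A and PARL, named after their positions were seen.

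Loci with a ZBTB24 promoter peak were then set beside the other listed loci of each table. The tables hold only loci that passed a filter on the fold change, so these comparisons describe listed loci and cannot show whether bound genes respond. In the knockdown, 118 of 1962 annotated loci (6.01%) were bound, while 982 of all 26281 reference genes (3.74%) were, a set not limited to tested genes. The bound loci had a median log2 fold change of 0.60 against 0.55 for unbound loci (permutation p = 0.266, adjusted p = 0.266). No absolute log2 fold change under 0.50 is listed for the knockdown, so both medians lie just above that limit. Of the bound loci in the authors' deposited table, 14 rose and 10 fell, with no difference in shares from unbound loci detected (Fisher's exact test, p = 1 for rises and p = 0.75 for falls). The bound loci that rose in the authors' deposited table included FAM111B (log2 fold change 2.70), the interferon-stimulated genes IFIH1 (1.87) and OAS3 (1.86), KLK10 (1.63) and MCM4 (1.59), of which IFIH1 and KLK10 were named after their values were seen, and those that fell included ATP8B3 (-2.16), VGF (-1.88) and MSMO1 (-1.11). With FLAG-ZBTB24 the 107 bound loci had a median of 0.53 against -0.52 (permutation p = 0.0591, adjusted p = 0.0985). That table holds no changes near 0, so its medians jump between the 2 sides, and the difference of means was 0.21 (permutation p = 0.0417). The 107 bound loci include the locus of MICAL1 and ZBTB24, the added gene itself (log2 fold change 3.12). No test without that locus was run, so how far the difference of means rests on it is not known. In the knockout, where only rises are listed, the medians were 1.42 for 108 bound and 2.17 for unbound loci. Genes with a DNMT3B peak had medians of 1.31 (217 bound loci) and 2.25 (unbound) in the knockout. In the knockdown the 661 loci with a DNMT3B peak had a median of 0.57 against 0.53 (permutation p = 0.107, adjusted p = 0.134). Their means differed by 0.13 (permutation p = 0.00773), and 61.0% of them had higher values against 52.0% of unbound loci (Fisher's exact test, unadjusted p = 0.000179, chosen after seeing the data). The same test of direction gave p = 0.128 for ZBTB24-bound loci in the knockdown and p = 0.162 with FLAG-ZBTB24 (Fisher's exact test).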

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

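The alternatives that count both labels of the knockout table, test the direction of lists and use all tables as background were chosen after seeing the data. Of 70 alternatives over 17 results, 59 kept the direction and the side of the threshold, or a count within 1.5 times. No paired analysis was possible because the tables hold pooled values per group, and for the same reason leaving out each replicate was not run. With a log2 fold change of at least 2, the knockdown count of 433 became 31, by the construction of the filter. Counting both labels of the knockout table gave 11 loci in place of 7, by adding 4 lower ones. With reference transcripts only, the DNMT3B promoter share was 0.754% and lay below placement; the cause was not tested. Without the 1% largest changes, r with the knockout was 0.0113 for the knockdown and -0.0437 for FLAG-ZBTB24, so Pearson's r rests on those loci in both, while rho for FLAG-ZBTB24 was -0.08 without and -0.10 with them. FLAG-ZBTB24 fold changes at bound promoters passed with a window of 2500 bp (difference of medians 1.07) and with means (0.21). In both, the bound loci include the locus of ZBTB24 itself. Fold changes of shZBTB24 at DNMT3B-bound genes passed with means (0.13). The cause of these differences was not tested. The 3 called list tests became 21 with a fold change of at least 1.5, 20 of 31 for the direction of all listed loci, and 5 of 13 for knockout rises against loci of all tables, which are different tests. S phase and G2 and M phase are among the lists called by fold change (the latter for fewer rises) and by direction. Depth limits could not be given, as the files hold no counts.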

Other observations

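The tests of interferon genes, of gene-body overlaps, of small RNA loci, of peak scores and of direction were chosen after the result was seen.

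In the knockdown, CDX2, a transcription factor of intestinal differentiation, rose from 6.90 to 18.8 FPKM in the authors' deposited table, while the cadherin gene CDH1 fell from 46.3 to 23.2 FPKM and SNAI2 from 2.41 to 0.743 FPKM. B2M (log2 fold change 0.79) and TAP2 (0.90), genes of antigen presentation, rose in the authors' deposited table.

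DNMT3B peaks lay towards the 3' end of genes. Of 15436 peaks inside reference transcripts of at least 2000 bp, 9632 (62.4%, 95% Wilson interval 61.6% to 63.2%) lay nearer to the 3' end than to the 5' end. With transcripts split into 10 equal parts, part 1 held 3.10% of the peaks and part 9 held 13.4%. Of 940 genes with a ZBTB24 promoter peak, 392 (41.7%) had a DNMT3B peak in the body, against 25.3% of other genes, with a Mantel-Haenszel odds ratio of 1.83 (95% interval 1.59 to 2.10) over 10 strata of gene length. Both kinds of binding may go with transcription, which was not adjusted for.

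Knockdown loci that were also listed as higher in the knockout were higher with the knockdown in 44.1% of cases, against 57.6% of other knockdown loci. All 9 listed oxidative phosphorylation loci were higher with the knockdown in the authors' deposited table, 3 of them past the threshold, and all 6 listed keratin loci were lower, with 1 past the threshold. After adjustment, no excess of called loci was detected for either list (adjusted p = 0.54 for oxidative phosphorylation rises and 1 for keratin falls, Fisher's exact test). Over the whole authors' deposited table, 240 of 1965 loci rose and 193 fell. In the test of direction, chosen after seeing the data, adjusted p was 0.0117 for oxidative phosphorylation and 0.0152 for keratin loci (Fisher's exact test). Among random lists matched on expression, the medians stood at percentile 84.1 for oxidative phosphorylation and 0.06 for keratin loci.

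Of the 33 listed interferon-stimulated loci, 25 rose with the knockdown, and 3 were past the threshold in the knockout. Binding by ZBTB24 at most of their promoters is argued against, since 2 of the 25 risen loci, IFIH1 and OAS3, had a promoter peak (8%, exact 95% interval 0.984% to 26.0%), beside 5.98% of other loci. A response to the hairpin vector cannot be told apart, because both arms of the knockdown carry a vector and wild type is 1 library. It is also not known whether the tables were normalized together. These 33 loci had a median log2 ratio of shNT over wild type of 0.63. For 134 other loci higher in both tables it was -0.22, a difference of 0.86. Both sets were chosen as higher in the knockout than in that same wild-type library, which favours low wild-type values and so higher ratios. With FLAG-ZBTB24, 18 of 20 listed interferon-stimulated loci had lower values in the authors' deposited table (Fisher's exact test of direction, adjusted p = 0.00195), and IFI27 fell there and rose with the knockdown. Loss of ZBTB24 stays open, as these values bear on it without deciding it.

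Few ZBTB24 peaks overlapped DNMT3B peaks. Their location outside gene bodies is argued against as the whole cause, because the 1721 ZBTB24 peaks in gene bodies gave 5 overlaps against a mean of 76.8 in placements within gene bodies, each of which gave at least 46. Removal of overlapping peaks when the lists were made is argued against as the whole cause too, because 72 of these peaks lay within 10000 bp outside a DNMT3B peak against a mean of 171 in placements (95% range 148 to 196). A difference in the chromatin that each factor binds was not tested.

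Of the 20 largest knockdown changes, 2 were at loci with microRNA or small nucleolar RNA genes, beside 33 of all 1965 listed loci. Short transcripts that make FPKM unstable are a candidate explanation that cannot be told apart. The median absolute log2 fold change of 33 such loci differed from that of 1932 others by -0.0555 (bootstrap interval -0.14 to 0.10, permutation p = 0.375). A difference of medians does not bear on the few largest changes, so this test cannot decide the question. No biological explanation was tested.

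The decimals of the ZBTB24 scores fit means of 2 or of 3 values with 5 decimals, within 0.01 and 0.05 of a step. By that reading 1406 peaks fit a mean of 2 values only, 2232 a mean of 3 only and 2535 either. Peaks that fit a mean of 3 lay at promoters more often, 19.5% against 16.7% (odds ratio 1.21, 1.01 to 1.44, Fisher's exact test, p = 0.0389). This reading of the scores may be wrong, since the kind of score is not given in the sources used here.

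On the X chromosome lay 0 of 6173 ZBTB24 peaks, which allows a share of up to 0.0486% by the limit of 3 counts and 0.0622% by the Wilson interval, and 17 of 15909 DNMT3B peaks (0.107%), while that chromosome makes up 5.02% of the annotated length. Neither list held a peak on the Y chromosome. Whether peaks there were filtered out when the lists were made is not known, so these shares are no result about binding. Among the lower loci of the knockout table, whose label DNMT3BKOshZB matches no sample given here, DNMT3B was listed at 21.1 FPKM in wild type and 6.46 FPKM under that label in the authors' deposited table, CDCA7 at 36.9 and 13.3 FPKM, and DNMT1 at 57.4 and 19.6 FPKM, none past the threshold. EREG (log2 fold change -7.55), SAT1 (-3.33), CYB5B (-2.91) and the locus of PHLDB2 and PLCXD2 (-2.66) were past it in the authors' deposited table.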
